A study of Mus musculus with 4 samples.

How the data were processed

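RNA was measured on 4 Affymetrix expression arrays, 1 per group. Per the labels, the cells were LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive bone marrow cells, a population that holds hematopoietic stem cells and multipotent progenitors) sorted from male C57/B6 mice aged 4 months. The groups were Ctrl and AMKO mice at day 0 (basal) and at day 8 after 150 mg/kg of 5-fluorouracil (5FU), a pyrimidine analog that kills dividing cells. The labels do not say what AMKO stands for, so it is used here as a genotype label. The targeted gene could not be read in the arrays for that reason, and the labels were not checked against it. The labels do not say how many mice were pooled for an array.

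The authors' deposited table held 1 value per probe set and array, which was read as log2 because the values lay between 1.99 and 13.43. The scale, the background correction and the normalization are not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit and biotin-labelled by the standard Affymetrix procedure. The medians of all values were 5.47 for Ctrl basal, 5.55 for AMKO basal, 5.43 for Ctrl day 8 and 5.44 for AMKO day 8. The deposited values were used without further scaling. For arrays, precision is limited by their number, and 1 array per group gives no replicate error.

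Of 34472 probe sets, 23521 were paired with 1 gene by the platform annotation, 1814 with several genes and 9137 with none. Symbols were updated through the Entrez identifier for 23328 of the probe sets with 1 gene, using a RefSeq gene table of GRCm38.p6 for names alone, and 193 kept the platform symbol. No gene was named from a probe set with several genes, and no coordinates are given. For the 1082 of 22180 genes with several probe sets, the probe set with the highest mean was used. A gene was kept when its highest value over the 4 arrays was at or above the median of all values (5.475 on the log2 scale), which left 14061 genes.

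The comparisons of 1 array with 1 array (5FU against basal in each genotype, AMKO against Ctrl at each time, and the difference of the 5FU differences) have no test. They are given as log2 differences and as counts of genes at least 2-fold higher or lower. The 5FU and AMKO effects averaged over the other factor were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 4 arrays, with additive terms for genotype and treatment. This model has 1 residual degree of freedom per gene and a prior of 2.62, and it takes any difference between the 5FU responses as error. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. They set an averaged effect against the difference between the genotypes' 5FU responses, combined with the prior, and not against a spread of replicates. That difference may be technical or biological.

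There were 37 gene lists, holding 968 distinct genes, of which 100 were not named by a probe set of 1 gene and 798 passed the floor. They covered the cell cycle, stem and progenitor cells, other marrow cell types, stress responses and metabolism. For a comparison of 1 array with 1 array, a list's median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of these arrays. For the additive model, limma's camera was run with an inter-gene correlation of 0.01, and again with an estimated correlation. Members were also counted past the gene test adjusted over the list alone. Genes move together within a list, so these list tests describe 4 arrays and not a population of mice.

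The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, among kept genes without predicted, microRNA, snoRNA or receptor-family symbols, the 10 highest and 10 lowest by the smaller of both genotypes' 5FU differences, both of 1 sign. It took 10 and 10 by the same rule for AMKO against Ctrl over both times, and 6 and 6 for AMKO at basal, for AMKO at day 8 and for the difference of the 5FU differences. Up to 4 members of each list described and 13 fixed marker genes, of which 11 were measured by a probe set of 1 gene, complete it. Ly6a, which encodes the Sca-1 sort marker, was among those without one.

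Alternatives were quantile normalization, centring each array on its median, no floor, a floor at the 75th percentile (7.32), the mean of a gene's probe sets, 1.5-fold and 3-fold sizes, and limma without a trend or with robust estimation. Left-out arrays (fitted with treatment alone), counts without genes of other cell types, and marker lists for muscle, heat shock and further blood cell genes were added after the data were examined. The additive fit was tested on simulated data with 14061 genes and 200 changed genes in each of 20 draws. It called 1.4% of genes changed by 1 on the log2 scale, 59.9% of those changed by 2, 88.4% of those changed by 3 and 97.5% of those changed by 4, with 6.26% false among the calls. These shares do not carry over to the real arrays, where the fit called 0 genes. There Cd48 and Sult1a1, with mean 5FU differences of 4.655 and -3.92, had an adjusted p of 0.0697 in limma. A simulated list shifted by 1 had an adjusted p of 2.18e-28 with camera, and 0 of 20 unshifted lists were called. This too does not show how camera performs on the real arrays, where genes move together within a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.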

Results

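Expression was measured in LSK cells of Ctrl and AMKO mice, before and 8 days after a dose of 5FU, with 1 array in each of 4 groups. The series design describes the dose as a means to activate hematopoietic stem cells. Spearman correlations between arrays, across probe sets, were 0.985 for both genotypes at basal and 0.977 for both genotypes at day 8. Across time the values were 0.966 in Ctrl and 0.974 in AMKO. There were no replicates, so no value below carries a replicate error. Standard errors given are those of the additive limma fit, which takes the difference between the 5FU responses of the genotypes as error.

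How LSK cells sorted at day 8 after 5FU differed from those sorted at basal was read in each genotype. For the genes and lists below, whether a difference lies within cells or in the mix of sorted cells was not tested. Cd48, a SLAM-family surface protein of committed progenitors, had log2 values of 9.96 in Ctrl and 9.49 in AMKO at day 8, against 4.99 and 5.15 at basal, which lie under the floor of 5.475. Plac8 was 17.3-fold and 8.94-fold higher, and Lgals1, a galactose-binding lectin, 11.2-fold and 18.5-fold higher. Among the lower genes, Sult1a1, a phenol sulfotransferase, was 14.5-fold lower in Ctrl and 15.8-fold lower in AMKO. Hoxb6, a homeobox transcription factor, was 8.28-fold and 6.73-fold lower.

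The rest of the 10 highest genes in both genotypes were Ms4a6c, Tespa1, Ctss, Ska3, Bex6, Cd53 and H1f5. Ska3, a kinetochore component, was higher by 2.45 in Ctrl and 2.48 in AMKO on the log2 scale, and Ctss, a lysosomal protease, by 2.53 and 2.45. Cd53, a tetraspanin of leukocytes, was higher by 3.05 and 2.32, and Tespa1 by 3.38 and 3.02. Ms4a6c (3.63 and 3.72) and the linker histone H1f5 (2.27 and 3.40) belong to gene families whose probe sets can share signal. The rest of the 10 lowest genes were Cldn5, Tc2n, Tns2, Pygm, Itgb3, Chrnb1, Spaca6 and Cxcl16. Log2 differences in Ctrl and AMKO were -2.99 and -3.44 for Cldn5, a tight junction protein, and -2.47 and -2.45 for Itgb3, the integrin beta chain of platelets. They were -4.36 and -2.83 for Tc2n, and -3.74 and -2.48 for Pygm, the muscle glycogen phosphorylase. Ms4a6c, Tespa1, Bex6 and H1f5 at basal, and Tc2n and Chrnb1 at day 8, lay under the floor in at least 1 genotype, so the sizes of their differences are uncertain. In the additive limma fit the standard error was 0.14 for Ska3 and 0.15 for Hoxb6, and these 20 genes had adjusted p between 0.0697 and 0.0732, so none passed, while all 20 passed with robust estimation. The 20 were chosen from the same arrays for large differences of 1 sign in both genotypes, which this fit favours. Their passing together is therefore no separate support.

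Genes of mitosis were higher after 5FU in both genotypes, with a median log2 difference of 1.43 in Ctrl and 1.35 in AMKO, above all 10000 random lists in each. Of 38 members, 36 in Ctrl and 37 in AMKO were at least 2-fold higher. Examples were the cytokinesis factor Ect2 (2.26 and 3.10) and the mitotic kinesin Kif20a (1.94 and 1.93). In limma's camera the adjusted p was 2.01e-23. It was 0.858 with an estimated correlation, a version that no list passed with its 1 residual degree of freedom. Adjusted over the list alone, 38 of 38 members passed, against 0 over all genes. DNA replication genes had medians of 0.83 and 0.95, with 16 and 14 of 39 at least 2-fold higher, among them Gins1 (1.61 and 1.97) and Rrm2 (1.59 and 1.77). Their camera adjusted p was 1.33e-17 (adjusted p = 0.858 with an estimated correlation), and 38 members passed adjusted over the list alone, against 0 over all genes. Mki67, a proliferation marker, was higher by 1.06 and 0.79.

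DNA repair genes had medians of 0.52 and 0.66, with Rad51ap1 and Brca1 among the highest on average; camera's adjusted p was 3.08e-05, and 17 of 33 members passed adjusted over the list alone. Oxidative phosphorylation genes had medians of 0.50 in Ctrl and 0.80 in AMKO, and 34 of 49 passed adjusted over the list alone, with a camera adjusted p of 2.27e-13. Uqcrq, of complex III, was higher by 1.07 and 1.29, and Cycs, cytochrome c, by 0.88 and 1.29. Ribosome biogenesis genes had medians of 0.31 and 0.50 (camera adjusted p 3.28e-05; 8 of 37 adjusted over the list alone). Each of these 3 lists had adjusted p = 0.858 with an estimated correlation and 0 members past the test over all genes. Pyrimidine metabolism genes had medians of 0.59 and 0.47 and a camera adjusted p of 0.0532, which did not pass. Tyms, the enzyme inhibited by 5FU metabolites, was higher by 0.66 in each genotype. The p53 target genes had medians of -0.05 and 0.09 (camera adjusted p 0.692), and the AMKO value became -0.05 after quantile normalization. Cdkn1a, a p53-induced cell cycle inhibitor, was higher by 0.40 in Ctrl and 1.10 in AMKO.

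Long-term stem cell genes were lower after 5FU in both genotypes. Of 32 members, 14 in Ctrl and 8 in AMKO were at least 2-fold lower, including Clec1a (-3.04 and -2.13), Neo1 (-2.23 and -1.78) and Ltbp3 (-1.96 and -1.91). The Ctrl count rests on an array with high markers of other blood cell types, described below, so the counts may not compare directly. The camera adjusted p was 5e-10 (adjusted p = 0.858 with an estimated correlation), and 21 members passed adjusted over the list alone, against 0 over all genes. The AMKO median of this list was -0.66, and -0.365 when a gene's probe sets were averaged. Procr, a stem cell surface receptor, differed by -1.64 and -0.70, Slamf1 by -0.48 and -0.36, and the sort marker Kit by -0.76 and -0.71. Cd34 was higher by 1.03 and 0.64, and Flt3, a progenitor cytokine receptor, by 1.57 and 0.52. Megakaryocyte genes, among them Mmrn1 and Itga2b, had a camera adjusted p of 0.000194 for lower values, with 8 of 20 members past the test adjusted over the list alone. Endothelial genes, among them Kdr and Robo4, had medians of -0.41 and -0.47 and a camera adjusted p of 0.00185. Both lists had adjusted p = 0.858 with an estimated correlation.

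**Figure D1:**
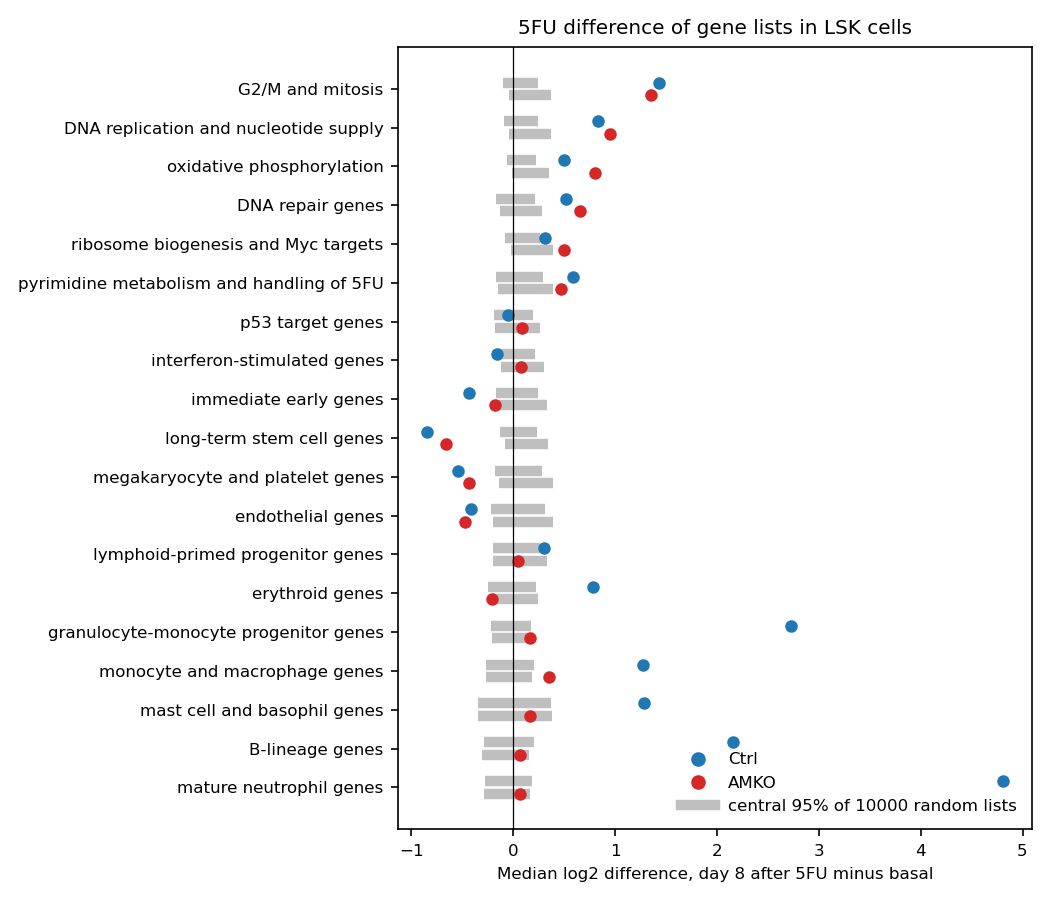
Median log2 difference of 19 gene lists between day 8 after 5FU and basal, in Ctrl (blue) and AMKO (red) LSK cells, 1 array per group; grey bars span the central 95% of 10000 random lists. Mitosis genes lie at 1.43 and 1.35, and mature neutrophil genes at 4.81 in Ctrl and 0.07 in AMKO.

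Markers of other blood cell types were high in the Ctrl day 8 array. Mature neutrophil genes had a median 5FU difference of 4.81 in Ctrl and 0.07 in AMKO, and 19 of 19 members in Ctrl and 2 in AMKO were at least 2-fold higher. Members such as Camp, Ltf and Retnlg passed the floor only through the Ctrl day 8 array, which raises the share in Ctrl. Granulocyte-monocyte genes had medians of 2.73 and 0.17, with Elane higher by 5.75 and Mpo by 5.03 in Ctrl. B-lineage genes were at least 2-fold higher for 12 of 14 members in Ctrl and 1 in AMKO, among them Ighm (4.68) and the transcription factor Ebf1 (3.89) in Ctrl. Itgam, a myeloid integrin, was higher by 4.32 in Ctrl and 0.20 in AMKO. For the 5FU average, camera's adjusted p was 0.00185 for neutrophil, 0.000267 for granulocyte-monocyte, 0.0108 for B-lineage and 0.00648 for monocyte and macrophage genes, each with adjusted p = 0.858 with an estimated correlation. Xist, expressed from the inactive X chromosome of females, had values of 4.23, 4.41, 7.65 and 3.97 in Ctrl basal, AMKO basal, Ctrl day 8 and AMKO day 8. A probe set shared by Xist and its antisense gene Tsix had values of 5.30, 5.14, 4.70 and 4.88.

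Over all 14061 genes, 706 were at least 2-fold higher and 627 lower in Ctrl, and 660 and 499 in AMKO. Centring each array on its median moved the AMKO differences by 0.12 and its split to 958 higher and 382 lower, or 71.5% against 56.9% higher; the mitosis median was then 1.46. Quantile normalization gave 556 higher and 553 lower in AMKO, or 50.1%, so the AMKO split depended on scaling. Among 4380 probe sets of no gene or several genes, more were lower than higher, with 168 higher and 280 lower in Ctrl and 202 and 267 in AMKO. Without 161 genes of the other-cell, granulocyte-monocyte and erythroid lists, the counts were 628 and 618 in Ctrl and 651 and 489 in AMKO. The additive limma fit called 0 genes for 5FU, with 3907 genes at an unadjusted p under 0.05, where chance gives 703. Quantile normalization, median centring, a floor at the 75th percentile and robust estimation gave 947, 161, 1293 and 1315 genes, while limma without a trend gave 0.

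How far the genotypes shared the 5FU differences was read across genes, which are not independent replicates. Pearson's r between the Ctrl and AMKO differences was 0.566 and Spearman's rho 0.621. Both genotypes had 276 genes at least 2-fold higher, where independent lists would share 33.1, and 279 at least 2-fold lower, against 22.3. There were 7 genes at least 2-fold different in opposite directions. No array enters both differences.

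**Figure D2:**
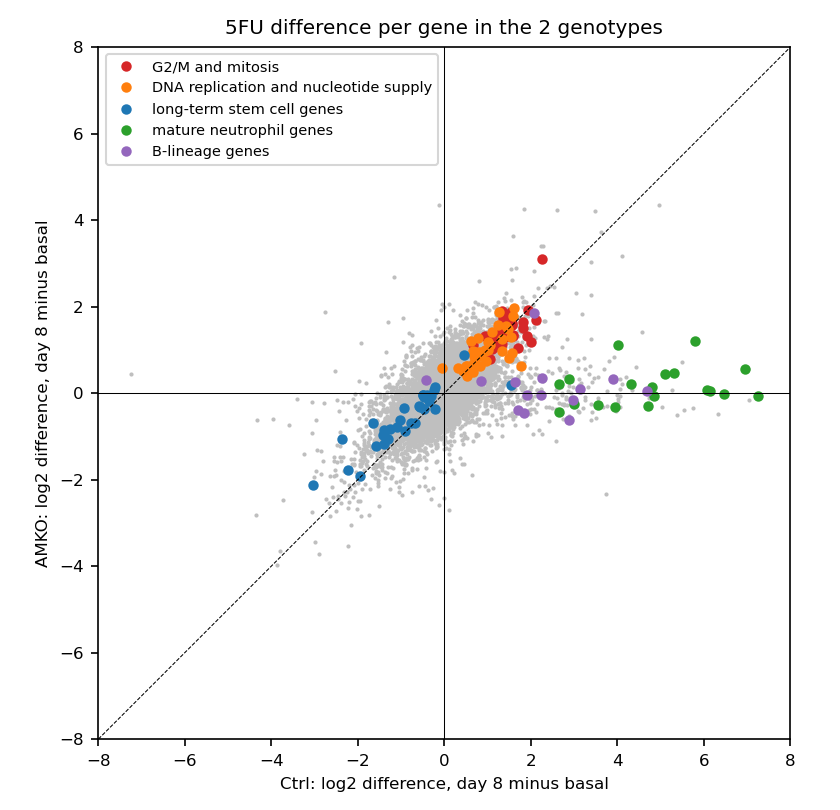
Log2 difference between day 8 and basal for each gene above the floor, in Ctrl (x axis) and AMKO (y axis), with members of 5 gene lists coloured; the dashed line marks equal differences. Mitosis genes lie in the upper right, while 19 of 19 neutrophil and 12 of 14 B-lineage genes are at least 2-fold higher in Ctrl, against 2 and 1 in AMKO. Some neutrophil genes, such as Camp, passed the floor only through the Ctrl day 8 array.

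AMKO and Ctrl LSK cells were compared at basal and at day 8. Immediate early genes, induced within minutes of stimulation, were higher in AMKO at both times, with medians of 0.52 at basal and 0.51 at day 8, above all 10000 random lists at each. Fosb, an AP-1 subunit, was higher by 0.90 and 3.46. The orphan nuclear receptors Nr4a1 (0.90 and 3.02) and Nr4a2 (1.09 and 2.34) were higher as well. Camera's adjusted p for the list was 1.88e-10 (adjusted p = 0.821 with an estimated correlation), 22 of 24 members were higher on average, and 1 passed adjusted over the list alone, against 0 over all genes.

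The other genes highest in AMKO at both times were Hspa1a, an inducible heat shock protein (1.04 and 3.04), Plek2 (1.02 and 1.05), Ptgs2, the inducible cyclooxygenase (0.80 and 1.30), Zfp36 (0.79 and 0.95), Mxra8 (0.99 and 0.78), Rasgef1b (0.77 and 0.99) and the histone H2aw (0.70 and 2.18). The lowest were Tnnc2 (-1.79 and -1.11), Sez6l2 (-2.43 and -1.10), Ckm (-2.95 and -0.91), 9930111J21Rik2 (-1.08 and -0.89), Scd1, a fatty acid desaturase (-0.89 and -1.40), Rpl32l (-0.88 and -1.01), Spo11 (-0.87 and -1.09), Camp (-0.85 and -8.16), Vcam1, an adhesion molecule (-0.85 and -1.19), and Actn3 (-2.37 and -0.83). Both basal values of Scd1 (5.39 and 4.50), Camp (5.05 and 4.20) and Vcam1 (5.25 and 4.40) lay under the floor, so their basal differences are uncertain. Hspa1a and Ptgs2 in Ctrl, and Ckm, Rpl32l and Actn3 in AMKO, lay under the floor at both times. Scd1, Spo11 and Camp did so in AMKO at day 8. The sizes of these differences are uncertain as well. Mxra8, Sez6l2 and Ckm had further probe sets with smaller basal differences. Their basal difference was 0.39 for Mxra8, -1.09 for Sez6l2 and -1.47 for Ckm when probe sets were averaged. The additive limma fit called 0 genes for AMKO (smallest adjusted p 0.906), with 446 at an unadjusted p under 0.05, fewer than the 703 that chance gives, and each of its alternatives also called 0.

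At basal, 32 genes were at least 2-fold higher and 98 lower in AMKO, a split of 24.6% higher that became 22 and 135, or 14.0%, after median centring. The highest were Mid1 (2.14), Rrp7a (1.77), Vldlr, a lipoprotein receptor (1.66), Magea3 (1.53), Cort (1.45) and Scarna17 (1.33). A second probe set of Rrp7a gave -0.32 and one of Mid1 gave 0.30. The lowest were Klk1b22 (-7.93), Myh4 (-4.11), Zfp982 (-3.66), Atp2a1 (-3.47), Acta1 (-3.31) and Ttn (-3.24). Magea3 and Cort in Ctrl, and Klk1b22, Myh4, Zfp982 and Ttn in AMKO, lay under the floor at basal. The sizes of their differences are therefore uncertain. Klk1b22 and Zfp982 belong to families of near-identical genes, and Klk1b22 was at 11.54 in the Ctrl basal array and at 3.61 to 4.30 in the others. Myh4, a fast myosin heavy chain, Atp2a1, the fast-fibre calcium pump, Acta1, skeletal actin, and Ttn, titin, are proteins of skeletal muscle. Over 25 skeletal muscle genes, listed after the data were examined, the Ctrl basal array lay a median of 1.64 above the mean of the other arrays, and over the 11 of them whose values had not been read it lay 0.58 above.

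At day 8, 104 genes were at least 2-fold higher and 370 lower in AMKO, or 104 and 299 without the genes of the other-cell, granulocyte-monocyte and erythroid lists. The lowest were the neutrophil granule genes Camp (-8.16), Ltf (-6.54) and Ngp (-6.26), the immunoglobulin gene Iglv1 (-6.77), and the receptors Lilrb4a (-6.33) and Fpr2 (-6.32), all but Ngp under the floor in AMKO. List medians were -4.93 for mature neutrophil genes and -2.13 for B-lineage genes, both below all 10000 random lists. They were -0.46 for dendritic cell and MHC class II genes. Long-term stem cell genes had a median of 0.33, above all 10000 random lists, against -0.01 at basal, within the central 95% of random lists. The day 8 value rests on the Ctrl day 8 array, where markers of other blood cell types were high. Whether that lowered stem cell genes in Ctrl was not tested. Camera for the stem cell list over both times had an adjusted p of 0.0658, which did not pass (0.887 with an estimated correlation). Camera's adjusted p over both times was 2.88e-09 for neutrophil, 7.54e-08 for granulocyte-monocyte, 6.71e-06 for B-lineage, 6.71e-06 for MHC class II, 0.0037 for monocyte and macrophage, 0.02 for erythroid and 0.0354 for mast cell and basophil genes. Each had adjusted p = 0.821 with an estimated correlation. The basal medians of these lists were 0.00 for neutrophil, 0.135 for granulocyte-monocyte, -0.02 for B-lineage, -0.12 for MHC class II, 0.015 for monocyte and macrophage, 0.16 for erythroid and -0.055 for mast cell and basophil genes, and only the erythroid value lay outside the central 95% of random lists. DNA replication (0.0171) and DNA repair genes (0.02) were higher in AMKO, with medians of 0.09 and 0.15 at basal and 0.18 and 0.14 at day 8, the last within the central 95% of random lists, and adjusted p = 0.821 with an estimated correlation. Sva, a seminal vesicle antigen gene, was the highest single gene (4.04), with 7.02 in the AMKO day 8 array and 2.68 to 3.10 in the others, and Fosb, Hspa1a, Nr4a1, Nr4a2 and H2aw followed.

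Across genes, the basal and day 8 AMKO differences had a Pearson's r of 0.0172 and a Spearman's rho of 0.0327. Of the genes at least 2-fold different, 3 were higher and 6 lower at both times, against 0.24 and 2.58 for independent lists, and 11 went in opposite directions.

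Whether the 5FU difference depended on genotype has no test with 1 array in each group. The AMKO minus Ctrl difference of the 5FU differences was at least 2-fold for 774 genes, 361 higher and 413 lower. Divided by the square root of 2, which puts it on the scale of a difference between 2 arrays, it was at least 2-fold for 104 higher and 256 lower genes. Without the genes of the other-cell, granulocyte-monocyte and erythroid lists the split turned to 360 and 341, and median centring gave 454 and 380. The lowest were Camp (-7.31), Iglv1 (-7.20), Fpr2 (-6.80), Ltf (-6.49), Lilrb4a (-6.47) and Retnlg (-6.38), all with 5FU differences of at least 6.32 in Ctrl. All lay under the floor in both basal arrays and in AMKO at day 8, so they passed it only through the Ctrl day 8 array. The sizes of these differences are therefore uncertain. The highest were Klk1b22 (7.68), Sva (4.46), Zfp982 (3.86), Myh4 (3.71), Atp2a1 (3.38) and Ttn (3.26). Of these, Sva was high in the AMKO day 8 array alone, and Klk1b22, Myh4, Atp2a1 and Ttn in the Ctrl basal array alone, where the last 3 were at 8.93, 9.49 and 8.09. Mitosis genes differed by a median of -0.035, which became 0.035 after median centring, and oxidative phosphorylation genes by 0.30.

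**Figure D3:**
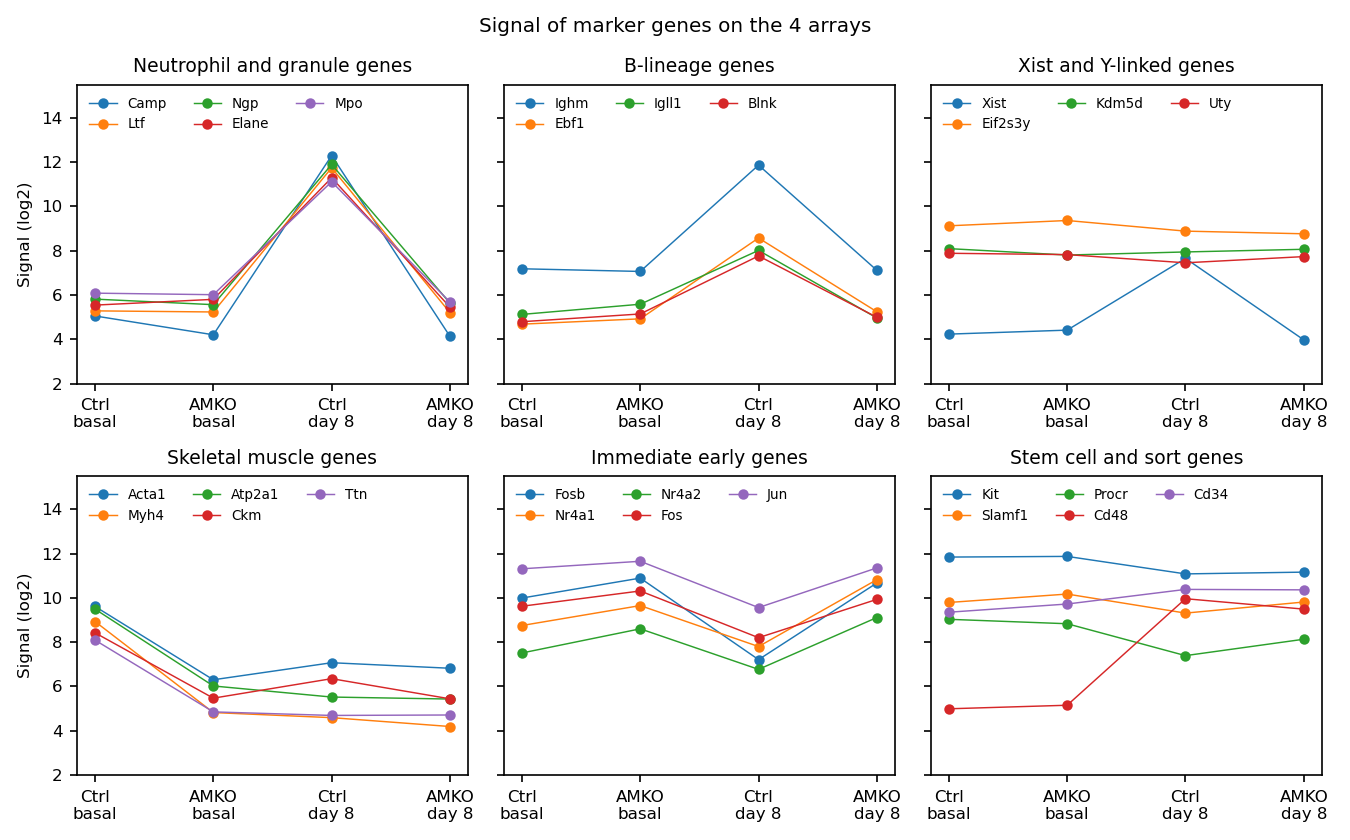
Signal (log2) of marker genes on the 4 arrays, 1 point per gene and array, with thin lines joining the points of a gene. Camp reaches 12.29 and Xist 7.65 in the Ctrl day 8 array, Acta1 9.61 in the Ctrl basal array, and the 3 Y-linked genes in the Ctrl day 8 array lie within 0.36 of the mean of the others.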

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

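Tests of scaling, of the sex of the animals and of mixed female RNA were chosen only after the result was seen, as were the patterns themselves, the use of the probe set shared by Tsix and Xist, a minimum of 1 on the log2 scale for opposite directions and a rule that takes shared globin probe sets only where they were higher; the second blood cell lists were written before their values were read.

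Zfp982 had a 5FU difference of -1.17 in Ctrl and 2.69 in AMKO, which is 3.86 apart in opposite directions, and this difference was not tested. Signals outside the genes analysed were also above basal in Ctrl. A probe set shared by Hba-a1 and Hba-a2 was higher by 2.55 in Ctrl and differed by -2.49 in AMKO, while another of these genes gave -0.04 and -1.01. A probe set shared by Hbb-b1, Hbb-b2 and Hbb-bs was higher by 3.54 in Ctrl and 3.39 in AMKO, while 2 others of these genes gave 1.17 and 0.52, and 0.58 and -0.09. The median of 5 probe sets of several immunoglobulin genes was 3.56 in Ctrl and -0.16 in AMKO. Xist was higher by 3.42 in Ctrl and differed by -0.44 in AMKO, although the labels give male mice. The probe set shared by Tsix and Xist differed by -0.60 in Ctrl. Of the further blood cell genes, 6 of 14 neutrophil, 6 of 11 B-lineage and 5 of 10 erythroid genes were above the floor in both basal arrays, and 0 stood in a list fixed earlier; of 25 muscle genes, 14 were above it and 1 (Tnni2) stood in the lymphoid-primed list. With 1 array per group, no array could be set against others of its group.

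Neutrophil and B-lineage genes and Xist were high together in the Ctrl day 8 array, as were 6 of 18 fixed erythroid genes, whose median 5FU difference of 0.785 became -0.04 with the floor at the 75th percentile. A scaling difference is argued against by the medians of all values, which lay between 5.43 and 5.55. The neutrophil list stayed 4.71 above the other arrays after quantile normalization, which could remove little with medians this close. A granulocyte-monocyte change alone is argued against by the fixed B-lineage list, with 12 of 14 members at least 2-fold higher after 5FU in Ctrl. A further 11 B-lineage genes, which lay 0.88 above the other arrays, add little to that list. A female animal in place of a male is argued against by 3 Y-linked genes, which lay within 0.36 of the other arrays. RNA from mature marrow cells that lineage depletion should have removed may account for part of the pattern. The smallest median excess of 3 further lists was 0.58 (10 erythroid genes). These lists hold more genes of cell types already seen high in this array. They cannot separate carried-over cells from such genes expressed within the sorted cells. Camp, Ltf and Ngp, at 12.29, 11.74 and 11.89, belong to the pattern that raised the question. Mixed female RNA stays open, since Xist, 3.24 above the highest other array, raised the question itself and its probe set shared with Tsix was lowest in this array (4.70), and so does a difference between genotypes in recovery after 5FU, which was not tested.

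Skeletal muscle genes were high in the Ctrl basal array, where Acta1 reached 9.61 and Atp2a1 9.49. For 11 muscle genes whose values had not been read, the median excess over the other arrays was 0.58, with a lower quartile of 0.47. RNA from skeletal muscle carried over into this sample, although the sort should exclude it, is a candidate explanation. The 11 are more genes of a tissue already seen high in this array. They cannot separate carried-over RNA from such genes expressed within the sorted cells. Members also differed: the median excess over all 25 muscle genes was 1.64, while it was 0.15 for Myl1 and -0.0033 for Ryr1. The 25 muscle genes had a median AMKO minus Ctrl difference of -1.48 at basal and -0.25 at day 8, and the 11 genes not read before -0.69 and -0.05. The lower AMKO values thus lay mostly at basal. A genotype difference stays open, since each group holds 1 array. The additive limma fit (adjusted p = 0.906 for Tnnc2, Ckm and Actn3) cannot decide, because it takes a difference at 1 time alone as error.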

How the results depend on the processing

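The left-out arrays and the counts without other-cell genes were chosen only after the result was seen. No paired analysis was possible because the groups hold 1 array each and the labels give no replicate numbers. The pseudocount alternatives were not run, since the values were already on a log scale. Of the values that answer a comparison, 81 stayed within their limits under an alternative, not counting the left-out arrays. For the 5FU average, limma called 0 genes, and 947 after quantile normalization, 161 after median centring, 1293 with a floor at the 75th percentile and 1315 with robust estimation (744 higher, 571 lower); the cause was not tested. It called 0 genes without a trend, without a floor and with averaged probe sets. With the Ctrl day 8 or the Ctrl basal array left out, the additive model has no residual degrees of freedom. A limma model with treatment alone, which leaves 1 array in an arm and assumes that it varies like the others, called 0 genes in each case and says nothing about dependence on that array. The floor at the 75th percentile leaves fewer genes and gave 74 genes for AMKO at basal, 260 for AMKO at day 8, 417 for the difference of the 5FU differences, and 10 lists past camera for 5FU against 16. At 1.5-fold the counts were 3352 for 5FU in Ctrl, 3636 in AMKO, 863 for AMKO at basal, 1332 at day 8 and 2465 for the difference; at 3-fold they were 482, 273, 36, 226 and 292. With an estimated correlation 0 lists passed camera for 5FU and 0 for AMKO. With 1 residual degree of freedom this was nearly fixed in advance. It cannot tell whether correlation between genes accounts for the lists. Of 925 list medians under alternatives, 60 had another sign than the value reported, 4 of them for lists outside the central 95% of random lists. Of these 4, mitosis genes in the difference of the 5FU differences became 0.035 after median centring. With the higher floor, lymphoid-primed genes became -0.14 and erythroid genes -0.04 for 5FU in Ctrl, and plasma cell genes 0.045 for AMKO at day 8. Of 828 values of single genes, 14 moved, all 14 with averaged probe sets, and 16 changed sign, none of a gene at least 2-fold different. Signal over background is not known for these values, so genes near the floor are the least certain.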

Other observations

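The heat shock, muscle and further blood cell lists were written only after the exploratory values of other genes were seen, and the test of heat shock genes was written before their values were read.

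Among lists not described above, surface genes reported to move on stem cell activation had a median 5FU difference of 0.46 in Ctrl and 0.46 in AMKO, with Cd48, Cd53 and Itgam the highest on average, Itgam at 4.32 in Ctrl and 0.20 in AMKO. The unfolded protein list had medians of 0.32 and 0.27, with Sdf2l1 higher by 1.59 and 1.35 and Mthfd2, a mitochondrial folate enzyme, by 1.59 and 1.14. Its camera adjusted p in limma was 0.024 (adjusted p = 0.858 with an estimated correlation). Antioxidant genes had medians of 0.13 and 0.43 and an adjusted p of 0.0234, and cytosolic ribosomal proteins 0.04 and 0.32 and 0.00955, each with adjusted p = 0.858 with an estimated correlation. The ribosomal protein medians lay within the central 95% of random lists in both genotypes. So did the antioxidant median in Ctrl and the unfolded protein median in AMKO. Immediate early genes had a camera adjusted p of 0.0155 for lower values after 5FU, with Egr1 at -1.75 and -1.19 (adjusted p = 0.858 with an estimated correlation).

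Interferon-stimulated genes had medians of -0.16 in Ctrl and 0.075 in AMKO, and the AMKO value became -0.04 after quantile normalization. Oas2 was higher by 1.76 and 1.40, while Gbp4 differed by -1.37 and -1.97. NF-kappaB and cytokine genes had medians of -0.01 and 0.00. Glycolysis genes had medians of 0.18 and 0.21, with the lactate transporter Slc16a1 higher by 0.70 and 1.75. Cholesterol synthesis genes had medians of -0.10 and 0.29. Camera passed none of these 4 lists. The homing list had medians of 0.43 in Ctrl and 0.20 in AMKO, with a camera adjusted p of 0.258 in limma, Itgal at 2.38 and 1.24, and Jam2 at -2.48 and -1.59. The cytokine receptor list had medians of 0.26 and 0.02, with Osmr at -2.32 and -2.06 and Il7r at 3.96 and -0.42.

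Immediate early genes were higher in both AMKO arrays. Heat or handling stress during preparation might give this pattern, and 10 heat shock genes whose values had not been read were set against it, 2 of which (Hspe1 and Hspd1) also stand in the ribosome biogenesis list. Their median AMKO minus Ctrl difference was 0.085 at day 8 and 0.065 at basal, with an upper quartile of 0.215 at each. Of these genes, Hspa1b was higher in AMKO by 0.28 at basal and 1.45 at day 8, and Dnajb1 by 0.68 and 0.51. Hspa1a, named above and not among the 10, was higher by 1.04 at basal and 3.04 at day 8, with both Ctrl values under the floor. These values lie between what stress and its absence would give, so the explanations cannot be told apart from 1 array per group. A genotype effect stays open. Camera passed the immediate early list for AMKO (adjusted p = 1.88e-10), while the version with an estimated correlation (adjusted p = 0.821), which no list passed, cannot decide.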
